A study of Rattus norvegicus with 24 samples.

How the data were processed

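Left ventricle from 24 male Wistar rats of 300 to 350 g was profiled on an Illumina rat bead array of 50-base probes with a Cy3 label, 1 array per animal. Rats had a sham operation or ligation of the left coronary artery and then ate normal chow or a high saturated fat chow, which makes 4 groups of 6 animals. Per the labels, the fat chow drew 60% of its calories from fat, of which palmitic acid made up 25%, stearic acid 33% and oleic acid 33%, and procedures took place 3 to 6 hours into the dark phase of a reversed light cycle. How long the rats were fed is not given in the sources used here. The animals are separate individuals, and nothing in the labels pairs them.

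The deposited signal of each probe is an intensity on a linear scale, the mean over its beads, exported with BeadStudio 3 per the submitters' processing notes and neither background-corrected nor scaled between arrays as far as the values show. A detection p-value accompanies each signal per the file headers, in steps of 1 in 825, which matches a rank among negative control beads. A second deposited table holds intensity values that the authors normalized, on a linear scale. Its 24 columns share the same distribution, and within each array the probes keep the rank order of the first table (Spearman correlation 1); which method the authors used is not stated. The non-normalized signals were used throughout, and the authors' normalized intensity served as an alternative.

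Signals were processed in R 4.3.3 with limma 3.58.1: background was corrected with neqc, which inferred the negative controls from the detection p-values, an offset of 16 was added, and arrays were quantile normalized and put on the log2 scale. Of 22517 probes, 10540 had a detection p under 0.05 on at least 6 arrays and were kept. Probe names came from the accession in the file for 6330 probes, from a current symbol for 4391 and from a synonym for 1404, all looked up in a RefSeq gene table of the rat; 10195 kept the name in the file and 197 had none. Where a gene had more than 1 kept probe, which applied to 137 genes, the probe with the highest mean signal was used. This left 10392 genes, of which 6614 carried an official symbol.

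limma was fitted to the 4 group means with 20 residual degrees of freedom and its default empirical Bayes settings. The 5 comparisons were ligated against sham on each diet, fat chow against normal chow in sham and in ligated rats, and the interaction of surgery and diet. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. All adjusted p-values of single genes are limma's, with n = 6 per group. Gene lists, 23 for pathways and 14 for cell types, were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the 37 lists of a comparison. Each was tested again with a correlation estimated per list, and with fry, a rotation test of whether a list moves on balance in 1 direction. Members of a list were also adjusted over the list alone. Overlaps between comparisons that share no animals were counted per direction beside the number that chance gives.

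The lists, tests, main settings and rule for naming genes were set before the data were examined. Per comparison the rule named the 6 largest rises and the 6 largest falls among called genes with an official symbol whose sign held with each array left out, the 3 members with the smallest p of each called list, and a set of 21 genes whatever their p; where fewer than 5 genes were called, the 5 with the smallest p were named. A gene outside the rule is introduced as chosen after its values were seen. Single-gene results of 3 genes are not reported here, although those genes count in the totals and lists.

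The arrays fell into 12 with a high background and 12 with a low one, judged from the signal of undetected probes. The files give neither a chip nor a date for any array, so this batch was read from the values alone. Every comparison was repeated with the batch as a fixed block and within each batch. Other alternatives covered background correction, normalization between arrays, the filter on dim probes, the variance model, array weights, which arrays entered the fit, the set test, each animal left out in turn, arrays that stood apart, and an index of clock genes as a covariate. The code was tested on simulated data built on the same arrays: for the comparison of surgery on normal chow, 96% of 50 genes changed by 1 on the log2 scale and 52% of 50 changed by 0.5 were recovered, and for the interaction 86% and 30%. The simulated noise was independent between genes and held no batch, so these shares test the code rather than power on the real arrays. Probes below the detection filter and genes without an official symbol outside the rule are not analysed here by name.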

Results

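Gene expression was measured in the left ventricle of 24 rats: 6 sham-operated rats on normal chow, 6 sham-operated rats on saturated fat chow, 6 rats with coronary ligation on normal chow and 6 with coronary ligation on saturated fat chow. Each array detected between 8884 and 10475 of 22517 probes, and the number of animals limits the precision. Correlations between arrays of the same group lay between 0.969 and 0.992, and no array was a copy of another. Background signal split the arrays into 12 at 132.2 to 148.5 and 12 at 77.2 to 87.5, called high-background and low-background arrays from here on. The high-background set held 2 sham chow, 3 sham fat, 2 ligated chow and 5 ligated fat animals. Surgery on chow was therefore balanced over the batches, while the ligated fat group was not. At an adjusted p under 0.05, 2159 genes (20.8%) differed between the batches.

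Ligation against sham on normal chow addressed how the failing ventricle differs when the diet is ordinary. Nppa, the atrial natriuretic peptide gene that the ventricle expresses under wall stress, rose by 2.71 on the log2 scale (SE 0.43, adjusted p = 0.0029), and 6 of 6 ligated animals lay above the sham mean. Nppb rose by 0.79 (SE 0.18, adjusted p = 0.0406) and the skeletal actin gene Acta1 by 1.25 (SE 0.27, adjusted p = 0.0315), both in 6 of 6 animals. Cacna1g, a T-type calcium channel gene of the fetal heart, rose by 1.72 (SE 0.25, adjusted p = 0.00218) and was above every sham animal in 6 of 6. Genes of matrix and attachment rose as well: Mfap4 by 0.70 (adjusted p = 0.00819), Fbln2 by 0.68 (adjusted p = 0.0174), Col8a1 by 1.38 (adjusted p = 0.03) and the LIM-protein gene Csrp2 by 1.58 (adjusted p = 0.00987).

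Several falls were as clear on chow. The mitochondrial thioredoxin gene Txn2 fell by 0.75 (SE 0.11, adjusted p = 0.00218), Pllp fell by 0.89 (adjusted p = 0.00432) and the ion transport regulator gene Fxyd3 fell by 1.20 (adjusted p = 0.00327), each below every sham animal in 6 of 6. Dgat1, which makes triglyceride, fell by 0.53 (adjusted p = 0.0264) and the carboxylesterase gene Ces1c fell by 1.31 (adjusted p = 0.0225). The other large rises were Mup5 at 1.85 (adjusted p = 0.02), the hepcidin gene Hamp at 1.57 (adjusted p = 0.0433) and Epn3 at 1.43 (adjusted p = 0.0031), and Uap1l1 fell by 0.48 (adjusted p = 0.03). Mup5 and Epn3 were each above background in 2 of 6 sham animals, which limits their values.

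The fixed gene lists placed these changes in 3 groups. Wall-stress and fetal genes were higher in 7 of 7, of which Myh7 and Ankrd1 read too close to the top of the scale to count as measured, with 3 called and 3 adjusted over the list alone (median 0.79, or 1.25 without those 2, camera adjusted p = 7.37e-06, adjusted p = 0.0249 with an estimated correlation). Matrix genes were higher in 36 of 42, with 2 called and 10 adjusted over the list alone (median 0.29, camera adjusted p = 6.05e-09, adjusted p = 0.21 with an estimated correlation). Fibroblast markers were higher in 13 of 13, with 1 called and 5 adjusted over the list alone (median 0.29, camera adjusted p = 4.57e-06, adjusted p = 0.0637 with an estimated correlation). The usual collagen markers were not called: Col1a1 differed by 0.19 (adjusted p = 0.906), Col3a1 by 0.29 (0.789), Postn by 0.33 (0.933) and Timp1 by 0.45 (0.597).

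Energy metabolism went the other way on chow. Of 27 genes of fatty acid uptake and oxidation, 1 was higher. None was called over all genes and 8 were lower adjusted over the list alone (median -0.25, camera adjusted p = 2.81e-11, adjusted p = 0.0604 with an estimated correlation). Acaa2, a member of this list, had a larger difference than its median (-0.70, adjusted p = 0.115). Acot1, which belongs to the PPAR-alpha-responsive list instead, differed by -1.21 (adjusted p = 0.0541) and was not called either. Acot1 was called without sham animal 15 (adjusted p = 0.0384) or ligated animal 38 (0.00661). Oxidative phosphorylation was higher in 9 of 53 (median -0.10, camera adjusted p = 1.35e-05, adjusted p = 0.0699 with an estimated correlation). The tricarboxylic acid cycle was higher in 1 of 17 (median -0.15, camera adjusted p = 0.001, adjusted p = 0.157 with an estimated correlation). Mitochondrial biogenesis and nuclear receptor genes were higher in 2 of 20 (median -0.14, camera adjusted p = 0.000248, adjusted p = 0.0375 with an estimated correlation), among them Ppargc1b at -0.71 and Ppara at -0.61. Lipid droplet and triglyceride genes were higher in 2 of 15 (median -0.13, camera adjusted p = 0.00331, adjusted p = 0.0249 with an estimated correlation). PPAR-alpha-responsive genes were higher in 10 of 26 (median -0.13, camera adjusted p = 0.00234, adjusted p = 0.175 with an estimated correlation). This list shares members with the oxidation list, Cpt1a and Ech1 among them, and with the lipid droplet list, such as Lpl. Calls of these lists are therefore not fully separate evidence in any comparison. Under median scaling the medians were lower, at -0.431 for fatty acid oxidation, -0.335 for the tricarboxylic acid cycle, -0.304 for oxidative phosphorylation and -0.23 for PPAR-alpha-responsive genes.

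Smaller lists were called beside them. Apoptosis and ceramide genes were higher in 12 of 17, with 4 adjusted over the list alone (median 0.14, camera adjusted p = 0.0033, adjusted p = 0.0249 with an estimated correlation), among them Bnip3 at 0.30, Bak1 at 0.27 and Casp9 at 0.22. Endothelial markers were higher in 12 of 13 (median 0.11, camera adjusted p = 0.0141, adjusted p = 0.0487 with an estimated correlation). Atrial markers were higher in 4 of 5 (median 0.11, mean 0.85, median 0.76 without a member near the top of the scale, camera adjusted p = 0.0479, adjusted p = 0.192 with an estimated correlation). The atrial list shares Nppa, which rose by 2.71, with the wall-stress list, so its call is not separate evidence. Adipocyte markers were higher in 1 of 8 (median -0.22, camera adjusted p = 0.0199, adjusted p = 0.21 with an estimated correlation). Sarcomere markers of cardiomyocytes were higher in 9 of 18 and were not called (camera adjusted p = 0.848), but 6 of the 18 read near the top of the scale, so the list says little about stability. Under median scaling the medians were 0.0749 for apoptosis and ceramide, 0.0401 for endothelial and 0.0196 for atrial genes. Macrophage markers were higher in 10 of 16 without a call (median 0.14, camera adjusted p = 0.183). Atp2a2 read at the top of the scale, and Myh7, Hba-a1 and Ankrd1, the last chosen after its values were seen, close to it. Changes in these genes could not be measured on any comparison.

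limma called 49 genes for surgery on chow, 37 higher and 12 lower, and camera called 13 of 37 lists, of which 5 held with an estimated correlation. With the batch as a block 60 genes were called, the 49 among them, and 12 lists. Within batches, which hold fewer arrays, 3 genes were called within the high-background and 0 within the low-background arrays, against the 49 in all arrays. At an unadjusted p under 0.05 in limma, all arrays gave 1081 genes where chance gives 519.6. Cacna1g differed by 2.04 and 1.57 and Txn2 by -0.72 and -0.77 in the high- and low-background arrays. The calls of Nppa, Cacna1g, Csrp2, Epn3, Mfap4, Fxyd3, Pllp and Txn2 held with each of the 12 animals left out. That of Nppb ended on leaving out any of 10, that of Hamp any of 11, those of Acta1 and Col8a1 any of 9, that of Uap1l1 any of 7, that of Dgat1 any of 6, that of Ces1c any of 5 and those of Fbln2 and Mup5 any of 3 (adjusted p up to 0.123). The adipocyte list lost its call without sham animals 7 (adjusted p = 0.0958) or 40 (0.0936) or ligated animals 16 (0.0578) or 24 (0.107), and the atrial list on leaving out any of 7 (0.0517 to 0.133), with a median of -0.011 without ligated animal 24. Median scaling gave 15 genes, 8 higher and 7 lower and 14 of them among the 49. The count ran from 24 without ligated animal 4 to 103 without ligated animal 21, and lay between 26 and 32 without sham animals 7, 9, 13 or 22 or ligated animals 16 or 24.

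**Figure D1:**
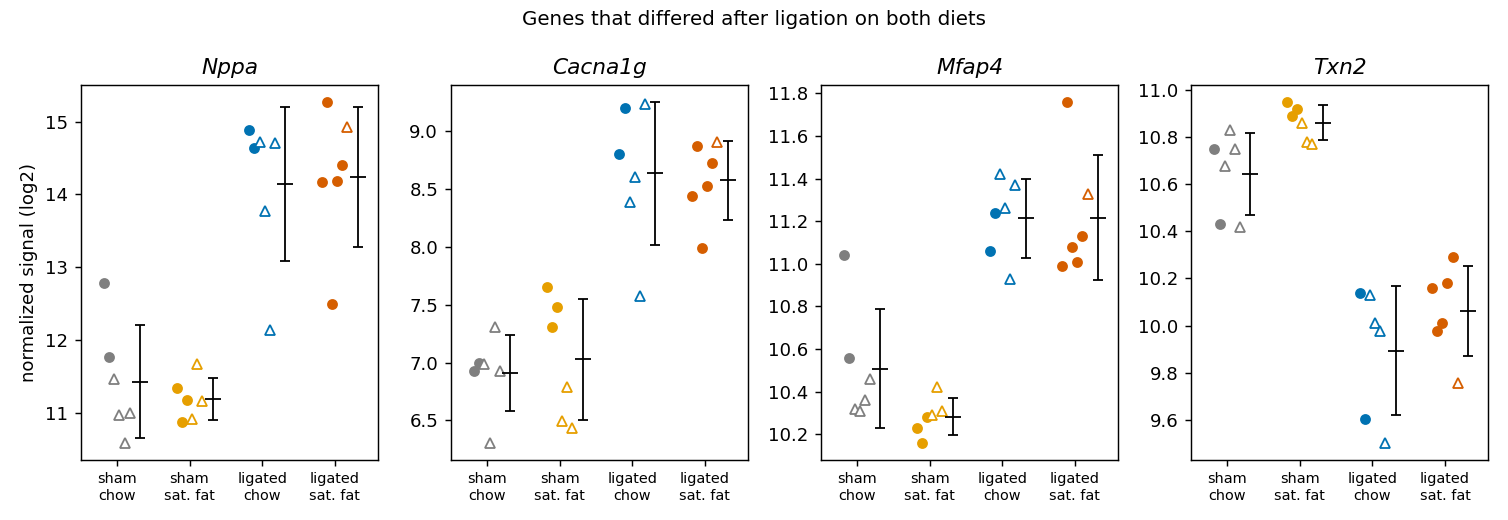
Normalized log2 signal of Nppa, Cacna1g, Mfap4 and Txn2 in each animal of the 4 groups; filled circles are high-background and open triangles low-background arrays, and the bar is the mean with its SD (n = 6). On saturated fat, 6 of 6 ligated animals lay above every sham animal for Nppa, Cacna1g and Mfap4 and below every sham animal for Txn2; on chow this held for 5 of 6 for Nppa and Mfap4.

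On saturated fat, ligation against sham addressed how the failing ventricle differs when the diet is rich in fat. Nppa rose by 3.05 (SE 0.43, adjusted p = 0.000984) and Nppb by 0.90 (SE 0.18, adjusted p = 0.0116), both in 6 of 6 ligated animals, and Cacna1g rose by 1.55 (SE 0.25, adjusted p = 0.00273). Matrix genes were among the larger rises, although the calls of Ltbp2, Ccn5, Cilp and Ccn2 ended with the batch as a block. Ltbp2, which binds elastic fibres, rose by 2.48 (SE 0.57, adjusted p = 0.0383), Ccn5 by 2.10 (adjusted p = 0.0455), Cilp by 1.56 (adjusted p = 0.0424) and the connective tissue growth factor gene Ccn2 by 1.13 (adjusted p = 0.044). Mfap4 rose by 0.93 (SE 0.13, adjusted p = 0.000984), and the fibroblast markers Pi16 and Cd248 rose by 1.43 (adjusted p = 0.0156) and 0.76 (adjusted p = 0.00739). Cilp was above background in 4 of 6 and Pi16 in 2 of 6 sham animals.

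All 3 chains of complement C1q, which tissue macrophages make, rose on saturated fat: C1qa by 0.86 (SE 0.17, adjusted p = 0.0117), C1qb by 0.67 (adjusted p = 0.0191) and C1qc by 0.70 (adjusted p = 0.0419). Hamp rose by 1.91 (adjusted p = 0.00739) and the mitochondrial carrier gene Ucp2 by 0.62 (adjusted p = 0.0419). The potassium channel gene Kcnk2 fell by 0.80 (SE 0.13, adjusted p = 0.00295) and the sodium channel gene Scn4b fell by 0.85 (adjusted p = 0.0219). Lsamp fell by 1.07 (adjusted p = 0.00273), Cyp2e1 fell by 2.14 (adjusted p = 0.026), Ddit4l fell by 0.88 (adjusted p = 0.0184) and the fatty acid oxidation gene Decr1 fell by 0.68 (adjusted p = 0.0383). Lsamp and Kcnk2 lay below every sham animal in 6 of 6.

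By list, matrix genes were higher in 40 of 42, with 4 called and 22 adjusted over the list alone (median 0.60, camera adjusted p = 8.67e-21, adjusted p = 0.0713 with an estimated correlation). Macrophage markers were higher in 16 of 16, with 3 called and 6 adjusted over the list alone (median 0.52, camera adjusted p = 3.47e-09, adjusted p = 0.0713 with an estimated correlation). Fibroblast markers were higher in 12 of 13, with 3 called and 8 adjusted over the list alone (median 0.37, camera adjusted p = 4.17e-10, adjusted p = 0.033 with an estimated correlation). Wall-stress genes were higher in 6 of 7, Myh7 and Ankrd1 again near the top of the scale, with 2 called and 4 adjusted over the list alone (median 0.69, camera adjusted p = 2.47e-06, adjusted p = 0.0225 with an estimated correlation). Atrial markers, which share Nppa with the wall-stress list, were higher in 4 of 5 (median 0.53, camera adjusted p = 0.000714, adjusted p = 0.0617 with an estimated correlation). The wall-stress median was 0.897 without Myh7 and Ankrd1. Under median scaling the medians of the wall-stress and fibroblast lists were 0.346 and 0.212. Postn (2.35, adjusted p = 0.135), Col1a1 (1.04, 0.148), Col3a1 (0.89, 0.168), Timp1 (0.71, 0.257) and Acta1 (0.99, 0.0847) were not called.

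Of the 6 metabolic lists called lower on chow, 5 were called lower on saturated fat. Lipid droplet and triglyceride genes were not, being higher in 5 of 15 (median -0.04, camera adjusted p = 0.333). Fatty acid uptake and oxidation was higher in 1 of 27, with 1 called lower and 12 lower adjusted over the list alone (median -0.26, camera adjusted p = 3.06e-10, adjusted p = 0.0885 with an estimated correlation). PPAR-alpha-responsive genes were higher in 5 of 26 (median -0.26, camera adjusted p = 0.00367, adjusted p = 0.193 with an estimated correlation). The tricarboxylic acid cycle was higher in 1 of 17 (median -0.17, camera adjusted p = 0.000829) and oxidative phosphorylation in 7 of 53 (median -0.10, camera adjusted p = 0.000529), both at adjusted p = 0.171 with an estimated correlation. Mitochondrial biogenesis was higher in 5 of 20 (median -0.12, camera adjusted p = 0.0313, adjusted p = 0.181 with an estimated correlation), with a camera adjusted p of 0.131 once the batch was a block and 0.099 under median scaling. Its call also ended without sham animals 12 (adjusted p = 0.0754) or 34 (0.0854) or ligated animals 28 (0.0754) or 37 (0.0529). Median scaling gave larger falls, with medians of -0.768 for fatty acid oxidation, -0.601 for PPAR-alpha-responsive genes, -0.756 for the tricarboxylic acid cycle and -0.796 for oxidative phosphorylation. With batch and clock index together the medians of the cycle and of PPAR-alpha-responsive genes were -0.0944 and -0.127.

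Surgery on saturated fat gave 92 called genes in limma, 63 higher and 29 lower, and 10 lists, of which 2 held with an estimated correlation. The batch as a block gave 57 genes, 53 of them among the 92, and 9 lists. Median scaling, which moved the median of all genes by -0.127, turned the balance to 13 higher and 88 lower, with 36 of the 92 called. The clock index as a covariate gave 45 genes, and 19 together with the block. The index averaged -2.86 in sham fat and -1.84 in ligated fat animals, so clock state was partly confounded with surgery on this diet. Within batches, 9 genes were called within the high-background and 4 within the low-background arrays, where the ligated fat group had 1 animal that is assumed to vary like the other groups. Blocking ended the calls of Ltbp2 (2.38, adjusted p = 0.0692), Ccn5 (1.83, 0.0867), Cilp (1.40, 0.0842), Ccn2 (1.09, 0.0805), C1qc (0.65, 0.0758), Ucp2 (0.56, 0.0764) and Fbln2 (0.51, 0.0672). Those of Nppa, Nppb, Cacna1g, Hamp, Mfap4, C1qa, Cd248, Lsamp and Kcnk2 held under the block and with each of the 12 animals left out. Leaving out single animals ended the calls of Ccn5 and Cilp for any of 11, Ccn2 for 10, Ltbp2 and Ucp2 for 9, C1qc, Decr1 and Fbln2 for 8, Cyp2e1 for 7, C1qb and Scn4b for 4 and Ddit4l for 3 (adjusted p up to 0.134). Pi16 lost its call without ligated animal 28 (adjusted p = 0.0509), and the count ran from 42 without that animal to 178 without ligated animal 18, with 43 to 55 without sham animals 11, 12, 17, 34 or 35 or ligated animals 37 or 39.

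**Figure D2:**
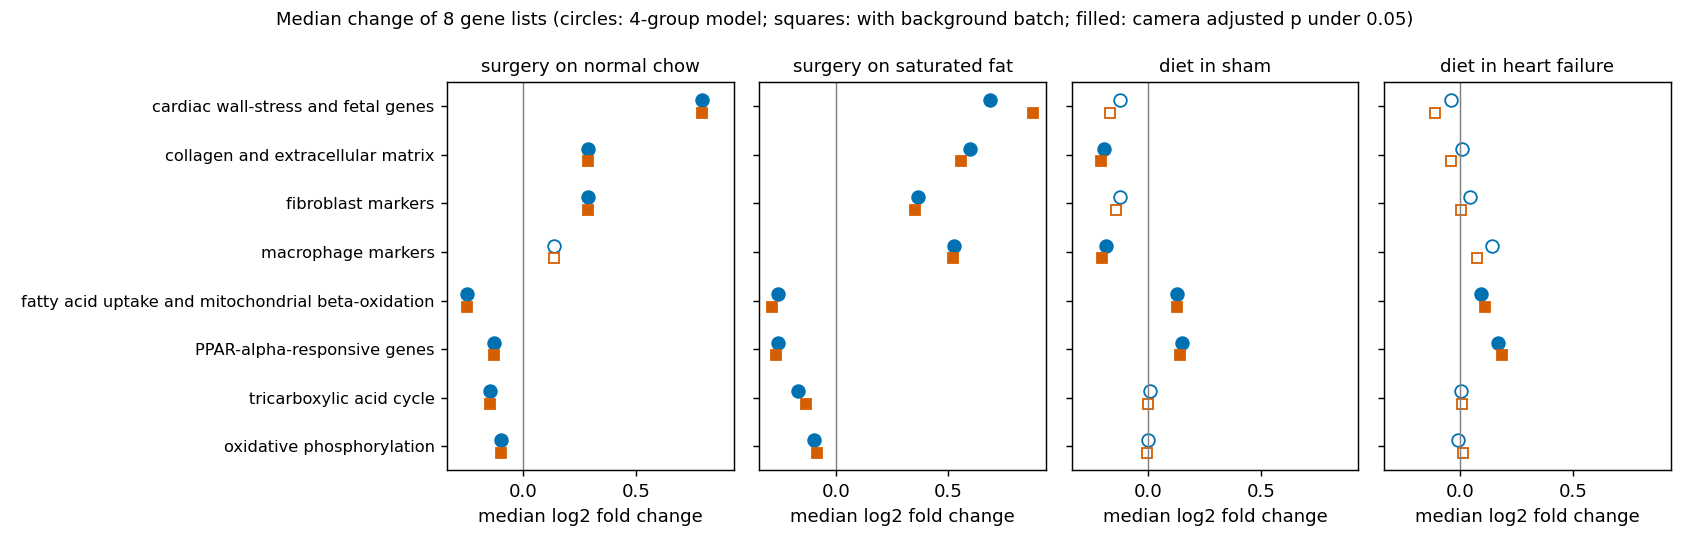
Median log2 fold change of 8 fixed gene lists in 4 comparisons, from the model of the 4 groups (circles) and with the background batch as a block (squares); filled symbols had a camera adjusted p under 0.05. Wall-stress, matrix and fibroblast genes lay above 0 and metabolic lists below 0 after ligation on both diets, while PPAR-alpha-responsive genes lay above 0 on saturated fat in sham and in ligated rats (below 0 in ligated rats under median scaling, at -0.124).

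Ligation changed many of the same genes on both diets, although the 2 comparisons share no animals. Both called 18 genes, 17 higher against 0.22 by chance and 1 lower, Txn2, against 0.03. Nppa, Nppb, Cacna1g, Csrp2, Mfap4, Fbln2, Hamp and Epn3 were among the 17. Of the others, chosen after their values were seen, the transglutaminase gene Tgm2 rose by 0.80 and 0.80 and Fstl3 by 0.81 and 0.67 on chow and saturated fat. With the batch as a block 15 genes were shared. Fold changes correlated across genes, which are not independent replicates, at 0.375, and at 0.441 with the block.

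Saturated fat against chow in sham hearts addressed what the diet does to a heart without infarction. Angptl4, a lipoprotein lipase inhibitor and PPAR target, rose by 2.23 (SE 0.34, adjusted p = 0.00956), and lay above every chow animal in 6 of 6, although it was above background in 4 of 6 chow animals. Other genes of the same programme were higher without a call: Acot1 by 1.16 (adjusted p = 0.313), Pdk4 by 0.90 (0.346), Ucp3 by 0.83 (0.497) and Decr1 by 0.68 (0.25), with 6 of 6 animals above the chow mean for Acot1, Pdk4 and Ucp3. Acot1 was called without sham chow animal 7 (adjusted p = 0.0479). PPAR-alpha-responsive genes were higher in 22 of 26, with 2 called and 9 adjusted over the list alone (median 0.15, camera adjusted p = 1.69e-09, adjusted p = 0.0319 with an estimated correlation). Their median was 0.0919 under median scaling and 0.0927 with batch and clock index together. Fatty acid uptake and oxidation was higher in 21 of 27, with 1 adjusted over the list alone (median 0.13, camera adjusted p = 0.000627, adjusted p = 0.71 with an estimated correlation), and was at -0.0104 under median scaling (camera adjusted p = 0.754). A second, dimmer Angptl4 probe (mean 6.03 against 7.31) differed by 0.22.

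Matrix and macrophage genes were lower on saturated fat in sham hearts. Matrix genes were higher in 8 of 42 with none called (median -0.19, camera adjusted p = 7.9e-05, adjusted p = 0.71 with an estimated correlation); Col1a1 differed by -0.96 and Postn by -1.57, both uncalled. The matrix list's median was -0.55 in high-background and -0.03 in low-background arrays, and without sham chow animal 15 its call ended (adjusted p = 0.182). Macrophage markers were higher in 3 of 16 (median -0.19, camera adjusted p = 0.0106, adjusted p = 0.71 with an estimated correlation), and that call ended without sham chow animals 15 (adjusted p = 0.169) or 22 (0.173) or sham fat animals 12 (0.0721) or 34 (0.0818).

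limma called 2 genes for diet in sham hearts, beside 620 at an unadjusted p under 0.05 where chance gives 519.6, and 4 lists, of which 1 held with an estimated correlation. With the batch as a block Angptl4 kept its call (2.17, adjusted p = 0.015). The count was then 1, as it was without any of 9 of the 12 animals, and it was 5 without sham chow animal 7. Neither batch alone called a gene. With the clock index as a covariate the calls of matrix (camera adjusted p = 0.216), oxidation (0.184) and macrophage genes (0.184) ended. The PPAR-alpha list's median was 0.14 with the block (camera adjusted p = 1.2e-08, adjusted p = 0.0535 with an estimated correlation), and 0.28 and 0.11 in high- and low-background arrays. Angptl4 was called with each of the 12 animals left out.

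Saturated fat against chow in ligated hearts addressed whether the diet has the same effect on the failing ventricle. Acot1, which splits fatty acyl-CoA and responds to PPAR-alpha, rose by 1.85 (SE 0.29, adjusted p = 0.0111) and lay above every chow animal in 6 of 6. Angptl4 was higher by 1.89 (SE 0.34, adjusted p = 0.0577), Pdk4 by 1.03 (adjusted p = 0.263) and Ucp3 by 0.81 (adjusted p = 0.503), all in 6 of 6 animals and none called. In ligated chow animals Acot1 was above background in 5 of 6 and Angptl4 in 3 of 6, and the second Angptl4 probe differed by 0.21. PPAR-alpha-responsive genes were higher in 20 of 26, with 1 called and 8 adjusted over the list alone (median 0.17, camera adjusted p = 1.99e-07, adjusted p = 0.09 with an estimated correlation). Fatty acid uptake and oxidation was higher in 22 of 27, with 1 adjusted over the list alone (median 0.09, camera adjusted p = 0.00485, adjusted p = 0.585 with an estimated correlation). Under median scaling both medians turned negative, at -0.124 for PPAR-alpha (camera adjusted p = 0.158) and -0.31 for oxidation (0.0109). Acaa2 (0.69, adjusted p = 0.503) had a larger difference than the oxidation list's median.

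Adipocyte and erythroid markers moved apart in the same comparison. Adipocyte markers were higher in 7 of 8, with 1 adjusted over the list alone (median 0.26, camera adjusted p = 0.0184, adjusted p = 0.493 with an estimated correlation), Aqp7 by 0.59 and Fabp4 by 0.22. Aqp7 also belongs to the PPAR-alpha-responsive list, and the 6 adipocyte markers outside that list had a median of 0.26. Erythroid markers were higher in 0 of 7 (median -0.32, camera adjusted p = 0.00485, adjusted p = 0.493 with an estimated correlation), with Ahsp at -0.90 and Hemgn at -0.41. Under median scaling the adipocyte list lost its call (median 0.125, camera adjusted p = 0.249) and the erythroid median was -0.61. Each list lost its call without single animals. The adipocyte list did so without ligated chow animals 16 (adjusted p = 0.0514) or 24 (0.118) or ligated fat animal 37 (0.077), and the erythroid list without ligated chow animal 21 (0.0589) or ligated fat animal 37 (0.0598). The oxidation list lost its call without ligated chow animal 24 (0.118).

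limma called 1 gene for diet in ligated hearts, beside 1002 at an unadjusted p under 0.05 where chance gives 519.6, and 4 lists, of which 0 held with an estimated correlation. With the batch as a block limma called 0 genes, Acot1 standing at 1.77 (adjusted p = 0.0803), and 6 lists, glycolysis (camera adjusted p = 0.0408) and lipid droplets (0.00879) being added. The PPAR-alpha list had a median of 0.19 with the block (camera adjusted p = 6.09e-09, adjusted p = 0.0464 with an estimated correlation). Within the low-background arrays, with 1 ligated fat animal, 1 gene was called, and within the high-background arrays 0. Acot1 lost its call without ligated chow animals 4 (adjusted p = 0.056) or 24 (0.0565) or ligated fat animal 5 (0.0513), and Angptl4 gained one without ligated chow animals 23 (0.00469) or 38 (0.0103) or ligated fat animal 28 (0.0425). Without ligated chow animal 38 the count rose to 7. The unnamed loci LOC302996 (1.11, adjusted p = 0.18), LOC300027 (1.15, 0.263) and LOC499745 (-0.62, 0.263) were next by p.

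**Figure D3:**
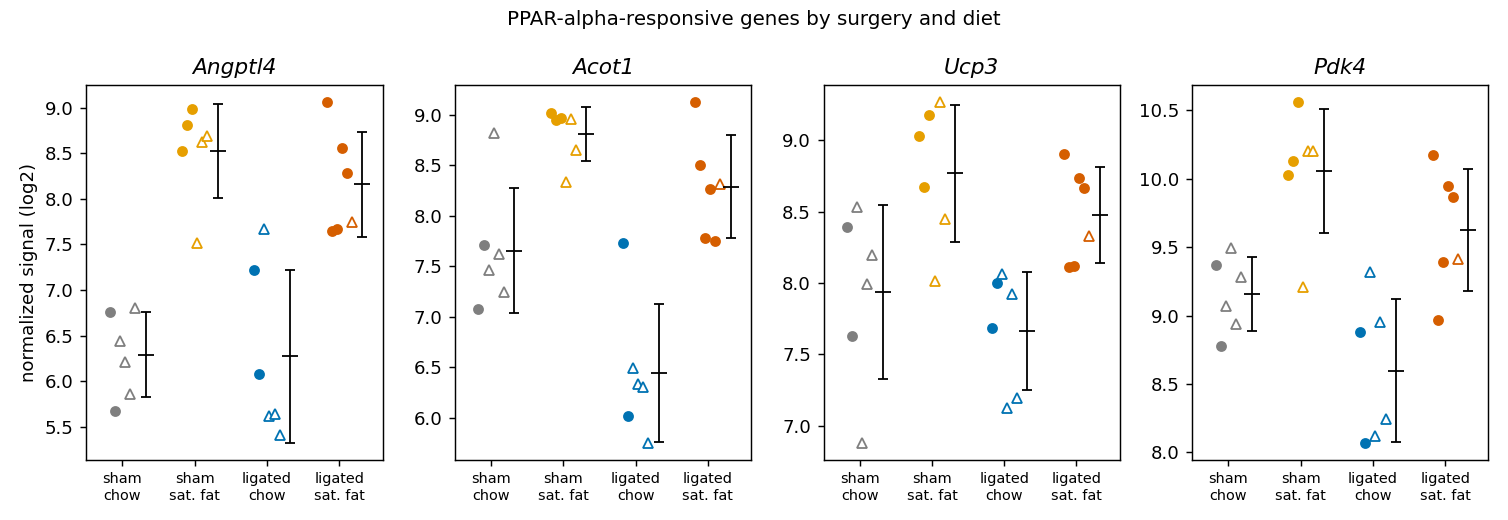
Normalized log2 signal of Angptl4, Acot1, Ucp3 and Pdk4 in each animal of the 4 groups; filled circles are high-background and open triangles low-background arrays, and the bar is the mean with its SD (n = 6). For each gene 6 of 6 animals on saturated fat lay above the mean of the chow animals with the same surgery. Angptl4 is drawn from its brighter probe, and the other differed by 0.22 in sham and 0.21 in ligated hearts.

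The diet effects in sham and ligated hearts shared 0 called genes, with 2 and 1 called in limma. At an unadjusted p under 0.01, 12 genes were higher in both against 0.84 by chance and 1 was lower in both against 0.52. Fold changes of the diet correlated across genes at 0.198, and at 0.052 with the batch as a block.

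The interaction addressed whether saturated fat alters the response to ligation. limma called 0 genes, with 563 at an unadjusted p under 0.05 where chance gives 519.6, and the smallest adjusted p was 0.673. The 5 genes with the smallest p were the unnamed locus LOC290569 at 0.78, above background in 1 of 6 sham fat and 2 of 6 ligated chow animals, and Pllp at 0.99 (both adjusted p = 0.673), Rab3b at 2.18, Stc1 at -0.83 and Nmi at 0.54. Postn (2.02, SE 1.01), Ppara (0.99, SE 0.34) and Col1a1 (0.85, SE 0.46) each had an adjusted p of 0.878. On genes simulated to change by 1 on the log2 scale, this comparison recovered 86%. Those genes were planted with many others in independent noise without a batch, which eases the adjusted threshold. The share therefore does not tell whether a real change of this size would be called, and Pllp at 0.99 was not.

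By list, the response of macrophage markers to ligation was larger on saturated fat in 16 of 16 genes (median 0.31, camera adjusted p = 0.000383, adjusted p = 0.656 with an estimated correlation). That of matrix genes was larger in 29 of 42 (median 0.27, camera adjusted p = 0.00811, adjusted p = 0.996 with an estimated correlation). Clock genes were higher in 2 of 10 (median -0.64, camera adjusted p = 0.0305, adjusted p = 0.656 with an estimated correlation), Tef at -1.52 and Per1 at -0.75. Bmal1 stood at 0.89, a value limited by background, since it was detected in 1 of 6 sham fat and 2 of 6 ligated chow animals. Erythroid markers were higher in 0 of 7 (median -0.24, camera adjusted p = 0.0375, adjusted p = 0.68 with an estimated correlation). With the batch as a block the macrophage list alone was called (camera adjusted p = 0.00181), against 0.0647 for matrix, 0.0675 for clock and 0.118 for erythroid genes. With the clock index as a covariate no list was called. The macrophage list stood at 0.259 (camera adjusted p = 0.0512). The median of the matrix list turned to -0.022, and to -0.0578 with batch and clock index together. Every gene of the index belongs to the clock list, so that list's loss of its call was largely built in. The index averaged -1.85 in sham chow, -2.86 in sham fat, -2.65 in ligated chow and -1.84 in ligated fat animals. It can therefore take up part of an interaction itself. The clock list lost its call without any of 12 of the 24 animals (adjusted p 0.0515 to 0.0921) and the erythroid list without any of 11 (0.0547 to 0.207), under median scaling (0.0556) and without Hba-a1 (0.106), although its median grew to -0.735 and -0.366. The matrix list lost its call without sham chow animal 15 (adjusted p = 0.323), ligated chow animal 21 (0.205) or ligated fat animal 28 (0.492), and the macrophage list kept its call with each of the 24 animals left out.

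**Figure D4:**
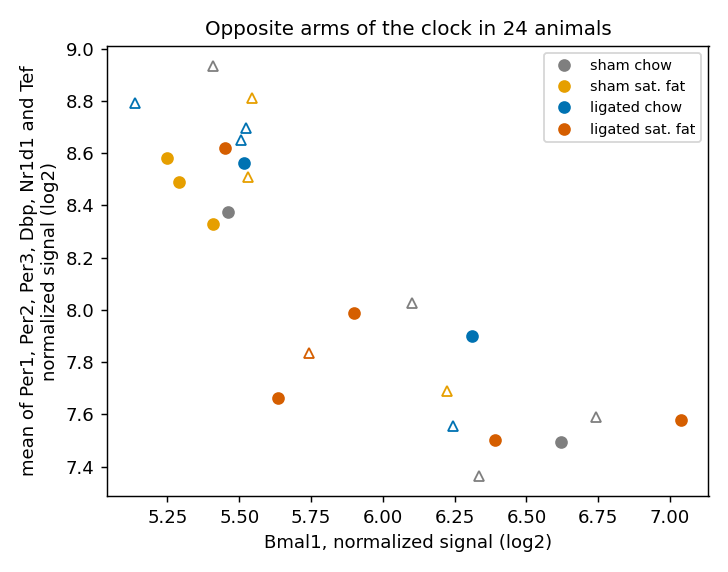
Bmal1 against the mean of Per1, Per2, Per3, Dbp, Nr1d1 and Tef in each of 24 animals, both as normalized log2 signal; colours mark the groups, filled circles high-background and open triangles low-background arrays. The 12 animals with a mean of 8.33 to 8.93 had Bmal1 at 5.14 to 5.54, not above background, and the other 12, at 7.37 to 8.03, had it at 5.63 to 7.04.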

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

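Of the tests in this part, the surgery score of animal 18 was fixed beforehand; the score bound for animals 15 and 21, the array quality of all 3, the clock tests and the tests on the PPAR-alpha list were chosen only after the result was seen. Among the 117 named genes and 4 groups, 49 of 468 sets of 6 animals had 1 animal apart, its gap to the nearest other animal exceeding Dixon's limit for 6 as a share of the group's range, where chance gives about 1 in 20 or 23.4. Ligated chow animal 21 accounted for 11 of the 49.

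Ligated chow animal 21 was lowest for Cilp (0.845 of the range), Ccn5 (0.815), Col8a1 (0.725), Timp1 (0.721), Ltbp2 (0.709), Nppb (0.681), Pi16 (0.651), Col14a1 (0.645) and Ccn2 (0.633), and highest for Slc2a4 (0.626) and for Hba-a1 (0.696), whose gap decides nothing so near the top of the scale. Sham chow animal 15 was highest for Pi16 (0.757), Ccn2 (0.669), Mfap4 (0.655) and Bak1 (0.631). Ligated fat animal 18 was lowest for Hamp (0.634) and highest for Aqp7 (0.72), Hsd17b10 (0.692) and Fh (0.636).

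Animals 15, 21 and 18 thus lay nearer to the other surgery than their groups did. A surgery score was the mean signed log2 difference over the 92 genes called in the other diet's animals. For animal 15 it was 0.256, above the other sham chow animals (-0.14 to 0.05). That was below the ligated chow animals other than 21 (0.591 to 0.873) by 2.85 of their SD. Exchanged labels would thus leave animal 15 out of place there too. Animal 21 scored 0.14, below animal 15. It lay above the sham chow animals other than 15 by 1.3 of their SD, which alone excludes no wrong label. Over the 49 genes called on chow, animal 18 scored 0.317, above every sham fat animal (highest 0.112) and below the other ligated fat animals (0.499 to 1.04), against a wrong surgery label. A poor array is argued against for animal 15, which had 9890 detected probes where the other high-background arrays had 9176 to 10475, but may apply to animals 21 and 18: the 8884 of animal 21 were the fewest of the low-background arrays (8972 to 9989 in the others) though its median correlation of 0.982 lay within theirs (0.978 to 0.989), while animal 18 had 9902 and the lowest correlation of the high-background arrays (0.979, others 0.985 to 0.991). The lowest correlation of the low-background arrays, 0.978, was that of ligated chow animal 4, so by the same measure its array may be poor too. A small infarct in animals 21 and 18 remains open and was not tested, since infarct size is not given in the sources used here.

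Clock genes set animals apart in every group. The mean of Per1, Per2, Per3, Dbp, Nr1d1 and Tef split them at its widest gap (0.30, the next being 0.15) into 12 animals at 8.33 to 8.93 and 12 at 7.37 to 8.03, and Bmal1, which peaks in the opposite phase, differed between these sets by -0.86 (permutation p = 1e-04, two-sided, 100000 resamples within groups; -0.92 and -0.79 in high- and low-background arrays; test value -0.855), which is a lower bound on the size since Bmal1 was not above background in the first set. Background is argued against, as each set held 6 arrays of either batch and the clock index of the batches differed by -0.00503 SD. The high set held 2 sham chow, 5 sham fat, 4 ligated chow and 1 ligated fat animals (Fisher's exact test, p = 0.126), so a different hour of collection within the stated window is a candidate explanation for the clock list in the interaction, and a true shift of phase by diet and surgery stays open, untested. The same imbalance lay across surgery on saturated fat, with 5 sham against 1 ligated animal in the high set. Clock state was thus partly confounded with that comparison. On chow the imbalance ran the other way, with 2 sham against 4 ligated animals.

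PPAR-alpha-responsive genes were higher on saturated fat in both surgery groups, except under median scaling in ligated hearts (median -0.124). Background was argued against: with the batch as a block the median was 0.142 in sham and 0.186 in ligated hearts, against 0.153 and 0.168 without it. Collection time was argued against as the whole cause, since with the clock index in the model the medians were 0.129 and 0.269 (camera adjusted p = 3.74e-08 and 1.43e-09, adjusted p = 0.105 and 0.0424 with an estimated correlation). Fat tissue in the piece and a response of the heart muscle cannot be told apart. The 6 adipocyte markers outside the list had a median of 0.153 in sham and 0.26 in ligated hearts, against 0.153 and 0.168 for the whole list. The 9 list members called in sham adjusted over the list alone had medians of 0.831 and 0.59, and their smallest differences were 0.357 and 0.0936. Those 9 were picked for their rise in sham, so their gap to the adipocyte markers is partly built in. Of the 6 markers, Cfd, an abundant adipocyte transcript, differed by -0.21 in sham and 0.34 in ligated hearts and Fabp4 by 0.27 and 0.22. Pparg differed by 0.42 and 0.30, Lipe by 0.43 and 0.30, Retn by -0.27 and -0.21 and Pck1 by 0.04 and 0.10. Retn (mean 6.06) and Pck1 (6.46) were the dimmest of them. A direct effect of dietary fat on the ventricle may explain the rise but was tested in no other way.

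The remaining values apart are given without explanation. Ligated fat animal 28 was highest for Cd68 (0.816), Col1a1 (0.786) and Pi16 (0.662) and lowest for Fabp4 (0.881) and Txnip (0.634). Ligated chow animal 4 was lowest for Ndufb7 (0.727), Cd248 (0.675) and Eci2 (0.628), animal 23 for Ndufs7 (0.859) and animal 38 for Myh7 (0.75), a gap that decides nothing near the top of the scale, while animal 38 was highest for Acot1 (0.627). Sham chow animal 7 was highest for Cs (0.649) and Acot1 (0.64) and lowest for Vwf (0.747) and Plin2 (0.638); animal 22 was lowest for LOC300027 (0.646) and Hbb (0.63), animal 40 was lowest for Mgll (0.754) and animal 9 was highest for Hemgn (0.649). Sham fat animal 12 was highest for Ddit4l (0.785) and Bmal1 (0.698) and lowest for Tef (0.71); animal 20 was highest for Aif1 (0.634) and lowest for Angptl4 (0.687) and Ppara (0.679). Of the other sham fat animals, 17 was lowest for Cs (0.785) and Txnip (0.688), 11 for Cd74 (0.738) and 35 for Hbb (0.679), and 34 was highest for LOC499745 (0.661).

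In the test of the interaction, 4 lists differed between the diets in their response to ligation: macrophage (camera adjusted p = 0.000383), matrix (0.00811), clock (0.0305) and erythroid genes (0.0375), none of them with an estimated correlation.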

How the results depend on the processing

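The alternatives that used the batch, the arrays that stood apart, the clock index and the top of the scale were chosen after seeing the data; the others were planned. The chip as a block was not run, since the files give no chip. No called gene among those named changed direction under any alternative or with any animal left out. For the largest rises and falls the part on animals left out was built in, since the naming rule required it. Without background correction, with normexp and an offset of 50, on the authors' values, with a detection p under 0.01, and with an intensity trend and robust variances, every count of genes and lists stayed within 1.5 times its value. Unless a reason is given, the cause was not tested. Bead signal over background limits dim genes, and Atp2a2, Myh7, Ankrd1 and Hba-a1 sat at the scale's upper end.

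With cyclic loess, 4 genes were called for diet in sham and 7 lists for diet in ligated rats. Median scaling gave 15 genes for surgery on chow, 0 for diet in ligated rats and 9 lists for the interaction; it moved the median of all genes by up to 0.127, in surgery on saturated fat, where 13 genes were higher and 88 lower, and it reversed the fatty acid oxidation list for diet in ligated rats (median -0.311). With no filter on dim probes, and so more tests, surgery on saturated fat gave 58 genes and diet in sham 1. Probes detected on all 24 arrays gave 0 genes for either diet comparison and 7 lists in sham. Array weights gave 120 and 307 genes for surgery on chow and saturated fat, and 4 and 3 for diet in sham and ligated rats. Fitting only the arrays compared gave 31 genes for surgery on chow, 6 for diet in sham and 0 for diet in ligated rats. The estimated correlation left 5, 2, 1, 0 and 0 lists in the 5 comparisons, and fry left 2 and 1 for diet in sham and ligated rats and 0 for the interaction. An unadjusted p under 0.01 in both gave overlaps of 13 genes for diet and 129 for surgery.

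The batch as a block gave 57 genes for surgery on saturated fat, 1 for diet in sham, 0 for diet in ligated rats and 1 list for the interaction. Fewer arrays lowered the counts within batches: the high-background arrays gave 3 and 9 genes for surgery on chow and saturated fat, 0 for either diet comparison, 7 lists for diet in ligated rats and 2 for the interaction, and the low-background arrays gave 0 and 4 genes for surgery, 0 for diet in sham, 1 list for diet in sham and 2 for the interaction. Without animals 15, 21 and 18, picked for their values so that counts rise in part by construction, surgery on chow gave 211 genes, on saturated fat 264 and in both 97; diet in sham gave 4 genes and 2 lists and the interaction 1 list. Without ligated chow animals 4 and 21, surgery on saturated fat gave 159 genes, the surgery overlap 43, diet in ligated rats 0 and the interaction 1 list. The clock index as a covariate gave 45 genes for surgery on saturated fat, 1 list for diet in sham and 0 for the interaction. In the interaction it reversed the matrix list (median -0.022), and the loss of the clock list was largely built in. Batch and clock index together gave 87 and 19 genes for surgery on chow and saturated fat, 9 in both, 0 genes and 8 lists for diet in ligated rats, 1 list for diet in sham and 1 for the interaction, and again reversed the matrix list there (median -0.0578).

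Of 43 calls of named genes, median scaling ended 22, no filter on dim probes 15, the batch as a block 9, the clock index 14 and both together 20, the high-background arrays alone 39 and the low-background arrays 42; array weights added 16 calls and leaving out animals 15, 21 and 18 added 20. Of 35 calls of lists, the estimated correlation ended 27, fry 13, the low-background arrays alone 13 and the high-background arrays 8, batch and clock index together 7, the clock index 6, median scaling 5, the block 5, probes detected on all arrays 3, no filter on dim probes and array weights 2 each, a detection p under 0.01 1, and leaving out members at least as bright as Myh7 1, the erythroid list of the interaction. Median scaling, the clock index and batch with clock index each also reversed 1. Without animals 15, 21 and 18 it was 6 calls that ended, and without animals 4 and 21 it was 4. With each animal left out in turn, surgery on chow gave 24 to 103 genes and 11 to 15 lists, surgery on saturated fat 42 to 178 genes and 9 to 13 lists, diet in sham 1 to 5 genes and 2 to 7 lists, diet in ligated rats 0 to 7 genes and 2 to 7 lists, and the interaction 1 to 4 lists.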

Other observations

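Of the tests in this part, the random regroupings were planned as a method but their bounds were set after the counts were seen, and those with the batch as a block were added later still. Several genes outside the main groups of the comparisons had values of interest. Pllp, a myelin-associated membrane gene, fell by 0.89 after ligation on chow (adjusted p = 0.00432). It was lower by a similar size on saturated fat in sham hearts (-0.77, adjusted p = 0.114, below every chow animal in 6 of 6). Both comparisons use the same sham chow animals, so the 2 falls are not separate evidence. After ligation on saturated fat, 3 animals lay above and 3 below the sham mean. The interaction value was 0.99 (SE 0.22, adjusted p = 0.673). Ppara, the receptor itself, was lower on saturated fat in sham hearts (-1.01, SE 0.24, adjusted p = 0.299) while its targets were higher, and stood at -0.02 in ligated hearts (adjusted p = 0.984). In sham hearts the antiviral gene Oas1k was higher on saturated fat by 1.55 (adjusted p = 0.0675) and the glucose-responsive gene Txnip by 0.53 (adjusted p = 0.155).

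Single genes of glucose and lipid handling from the fixed set were not called for diet. The glucose transporter gene Slc2a4 differed by 0.12 in sham and -0.16 in ligated hearts, the desaturase gene Scd, above background in 3 of 6 animals of 3 groups, by 0.19 and 0.08 and the lipid droplet gene Plin2 by -0.07 and -0.01. Cpt1b, the muscle form of carnitine palmitoyltransferase, differed by -0.04 and 0.07, whereas Cpt1a was higher by 0.41 in sham (adjusted p = 0.601) and 0.09 in ligated hearts.

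Animals of the groups compared were regrouped at random, 100 splits per result with the real one included. For surgery on chow, chance can be excluded for the 49 genes: 2 of 100 splits gave as many, and the highest other, 125, parted 0 from 4 high-background arrays and called 0 with the batch as a block, so it followed the batch. The blocked count was 60 (1 of 100, highest other 2). For surgery on saturated fat it can be excluded for the 92 genes (1 of 100, highest other 2) and for the 57 with the block (1 of 100, highest other 4), and for the 18 genes shared by both (1 of 100, highest other 0). These splits cannot part surgery from clock state, which differed between sham fat and ligated fat animals. For diet in sham no other split reached the count of 2 genes (1 of 100, highest other 1). So small a count cannot exclude chance for each of the 2, and it fell to 1 without any of 9 animals. With the block the count was 1, reached in 3 of 100 (highest other 1). For diet in ligated rats chance cannot be excluded for the 1 gene: 10 of 100 splits gave as many, the highest other calling 213 genes with 6 against 1 high-background arrays. With the block that split called 0, so it followed the batch, and the real count was 0. The interaction's 0 genes (highest other 1) and the 0 genes shared by both diet effects (highest other 0) are reached by any split, here 100 of 100, so the regroupings decide nothing there. The 13 genes shared at an unadjusted p under 0.01 were reached in 2 of 100 (highest other 15, parting 5 from 0 high-background arrays in 1 of its comparisons). For the correlation of the diet's fold changes, 0.198, chance cannot be excluded (16 of 100, highest other 0.568). That of surgery, 0.375, was reached in 3 of 100, with the highest other at 0.386, above the real value. This argues against chance without excluding it, and these splits were not repeated with the block.

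For the number of gene lists chance cannot be excluded in any comparison: 6 of 100 splits gave the 13 lists of surgery on chow (highest other 14), 6 the 10 lists on saturated fat (13), 31 the 4 lists of diet in sham (10), 39 the 4 in ligated rats (12) and 27 the 4 of the interaction (9). For single lists, not corrected for their number, the PPAR-alpha list had a camera p as small in 2 of 100 splits in sham (4.57e-11, smallest other 1.48e-11) and 3 of 100 in ligated rats (5.39e-09, smallest other 8.69e-11). With the block this was so in 1 of 100 in sham (3.23e-10, smallest other 3.61e-10) and 1 of 100 in ligated rats (1.65e-10, smallest other 2.09e-09). The margin in sham was narrow. With the real split included, 1 of 100 is the lowest share that can occur, too coarse to allow for the 37 lists tested. With the block, splits were run for no list but the PPAR-alpha list. They argue against chance for that list taken alone, without showing that chance can be excluded. For the clock list of the interaction it cannot (9 of 100; 0.00247, smallest other 2.45e-05). The wall-stress list was reached by 1 of 100 splits on either diet, the matrix list by 11 on chow and 2 on saturated fat, and the fatty acid oxidation list by 5 and 2. Among the other lists of surgery, adipocyte markers on chow were reached by 15, atrial markers on chow by 8, the PPAR-alpha list by 5 on chow and 8 on saturated fat, and mitochondrial biogenesis and oxidative phosphorylation on saturated fat by 7 and 5. For diet in sham, matrix genes were reached by 21, macrophage markers by 22 and fatty acid oxidation by 15. For diet in ligated rats, oxidation was reached by 26, adipocyte markers by 10 and erythroid markers by 7, and in the interaction matrix genes by 35, erythroid markers by 18 and macrophage markers by 9. Chance cannot be excluded for any list reached by 5 or more.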
